A study of Limosilactobacillus reuteri subsp. reuteri F275 with 2 samples.

How the data were processed

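Total RNA of Limosilactobacillus reuteri F275 was measured on 2 two-colour arrays. Per the labels' protocols, cells were quenched in cold buffered methanol, broken with glass beads in phenol and chloroform, and RNA was purified on columns with DNase treatment. It was reverse transcribed from random nonamers with aminoallyl-dUTP, and the cDNA was coupled to Cy3 or Cy5. Per the labels, one array carried Glu in Cy3 and Gly in Cy5, and the other the reverse. They are called array 1 and array 2 here, in the order of deposit, which is not the numbering in their titles: the array titled with the number 1 is array 2 here. The digits after the conditions in the titles follow the dyes and number no cultures, so whether the arrays share RNA is not given in the sources used here.

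The deposited scanner files hold the intensity of each spot and of its local background on a linear scale, quantified with ImaGene and neither background-subtracted nor normalized, per the file headers. Each file also holds a quality flag per spot and channel. The authors' deposited value table holds log2 ratios for the 10263 gene spots, and limma is named in the submitters' processing notes, with no version. The scale and direction of the table were settled by comparison with the scanner values. Its columns had correlations of 0.9997 and 0.9998 with log2 of Cy3 over Cy5 after background subtraction. Their medians were 0.05 and -0.07, shifted by -0.01 and 0.01 against those scanner values, so little or no centring is visible, and the step that made these small shifts is unknown.

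From the scanner files, spot means were background-corrected with normexp (offset 50) on the local background medians, and log2 ratios were normalized within each array by loess over unflagged gene spots with limma 3.58.1 in R 4.3.3. Control spots and spots flagged by ImaGene in either channel were then left out, 277 (2.70%) of the gene spots on array 1 and 208 (2.03%) on array 2. Ratios were turned to Gly over Glu on both arrays. A gene's value on an array was the mean over its remaining spots, which come from 9308 probes for 1683 genes, 618 of these probes with more than 1 spot. Probes of a gene differed by a median SD of 0.19 on array 1 and 0.14 on array 2 over its spots. 3 genes without an unflagged spot on both arrays were not tested, and 31 tested genes had fewer than 3 spots left on an array.

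The mean of both arrays was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 1680 genes. With 1 residual degree of freedom per gene, the fit took its spread from all genes together. On simulated data with 200 changed genes of 1680, the test recovered 74% of the changes of 0.5 on the log2 scale and 100% of those of 1, 2 and 3. Among 1480 unchanged genes 14 were called, 6.97% of the 201 calls. The simulated noise was drawn independently between genes, with the same SDs for all genes. In the data the spread between arrays rose with brightness, so these rates may not hold for the real genes. Permutation tests on runs of ID numbers used 10000 permutations and were chosen after the ratios were seen. Figures were drawn with matplotlib 3.10.9.

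Design, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those stated to be chosen later. The rule took the 10 called genes with the largest mean ratios in each direction that have a name, members of fixed gene lists and the dehydratase genes, and allowed at most 2 IDs per direction where genes have no name. None of the 1683 IDs matched the 2047 genes of the RefSeq gene table at hand, which is of the assembly of another strain, and the files do not pair IDs with names. Only the last part of the rule was therefore used, and the lists for glycerol use, cobalamin synthesis, glycolysis and other pathways were not tested. Genes were described by neighbouring ID numbers in their place. Alternatives varied the background correction, the normalization, the spot summary, the filters, the averaging over spots, the test and the arrays used. The array's spots formed 1 block, so loess within printing blocks was not run, and each array was its own slide, so no slide block applied.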

Results

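The series compared RNA of Limosilactobacillus reuteri F275 from a late logarithmic condition labelled Gly with RNA from one labelled Glu. This gut lactic acid bacterium converts glycerol to reuterin, an antimicrobial aldehyde, through a cobalamin-dependent dehydratase. The title of the series concerns what glycerol does to its metabolism, so Gly was read as glycerol. What Glu stands for, and what else the media held, is not given in the sources used here. Both RNAs were hybridised together on each of 2 arrays with the dyes exchanged. Gly was in Cy5 on array 1 and in Cy3 on array 2, numbered in the order of deposit and not as in their titles. Each array held 10263 spots for 1683 genes, with a median of 6 spots per gene. The median intensity of the gene spots above local background was 646 for Glu and 647 for Gly on array 1. It was 477 for Glu and 476 for Gly on array 2. At least 99.97% of the gene spots exceeded the local background by 2 background SDs in each channel. The labels number no cultures, and the arrays may share RNA. All p-values of the limma fit therefore measure the spread between 2 arrays, pooled over all genes, and the number of arrays limits the precision. If the arrays share RNA, no p-value measures variation between cultures. A called gene could then differ between the RNA samples used and not between the conditions in general.

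Gly and Glu cells differed most in a small number of genes with ratios far beyond the spread between arrays. The largest increase with Gly was that of LR1RLRE00092, with a mean log2 ratio of Gly over Glu of 4.90 ± 0.44 (SD, n = 2), or 29.9-fold. Its mean intensity above background was 21703 with Gly and 1029 with Glu. These intensities, here and for the genes below, average all spots, flagged ones included, and are not normalized. The log2 ratio of LR1RLRE00092 rests on 2 unflagged spots on array 1 and 1 on array 2 of 6 spots each. It was 4.85 with flagged spots kept. LR1RLRE01360 was 15.3-fold higher with Gly, at a log2 ratio of 3.93 ± 0.30 (SD, n = 2) and with intensities of 9649 and 841. The largest decrease with Gly was that of LR1RLRE00555, at a log2 ratio of -3.32 ± 0.15 (SD, n = 2). It was 9.96-fold higher with Glu, with an intensity of 18799 against 1502 with Gly. LR1RLRE00827 had a log2 ratio of -2.85 ± 0.26 (SD, n = 2) and was 7.20-fold higher with Glu, at 3751 against 492. Without background correction the log2 ratios of the 4 genes, in the order given, were 4.06, 3.22, -2.89 and -1.92. The array files pair no gene names with these IDs, and 0 of the 1683 IDs matched the gene table at hand. The functions of these genes, and the behaviour of the dehydratase genes, were therefore not analysed here.

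Of 1680 genes tested, 341 (20.3%) passed limma's test at a Benjamini-Hochberg adjusted p under 0.05. Among them 208 were higher with Gly and 133 were higher with Glu, and all 341 had the same sign on both arrays. Most of the changes were small. The median log2 ratio was 0.66 among genes higher with Gly and -0.55 among genes higher with Glu, and the smallest called size was 0.42. A mean change of at least 2-fold was found for 49 genes higher with Gly and for 14 higher with Glu. At least 4-fold changes were found for 25 and 4 genes. On both arrays alike, 42 genes were at least 2-fold higher with Gly and 11 at least 2-fold higher with Glu, 53 in all. The fit took a single SD of 0.233 for every gene, so that each mean log2 ratio had an SE of 0.16. A call therefore depended on the size of the mean alone and could rest mainly on 1 array. A gene called higher with Gly, for example, had log2 ratios of 0.97 on array 1 and 0.03 on array 2. The adjusted p of the 4 genes named above ran from 8.84e-154 to 2.04e-59 on this pooled spread, and each had the same sign on 2 of 2 arrays. The split of the calls depended on the scaling, with 164 genes higher with Gly and 146 higher with Glu after median centring, 139 and 190 without normalization, 141 and 189 in the authors' value table, and 741 and 19 after centring on the E1A control spots, a setting chosen after seeing the data. The number of calls fell to 179 without background correction and to 201 with the median of each spot's pixels. With the median over each gene's spots 232 genes were called. LR1RLRE00092 kept its log2 ratio of 4.90 there, yet its adjusted p in limma's test was 2.28e-06. The size of an adjusted p thus depended strongly on the spread that the fit estimated, and not on the ratio alone.

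**Figure D1:**
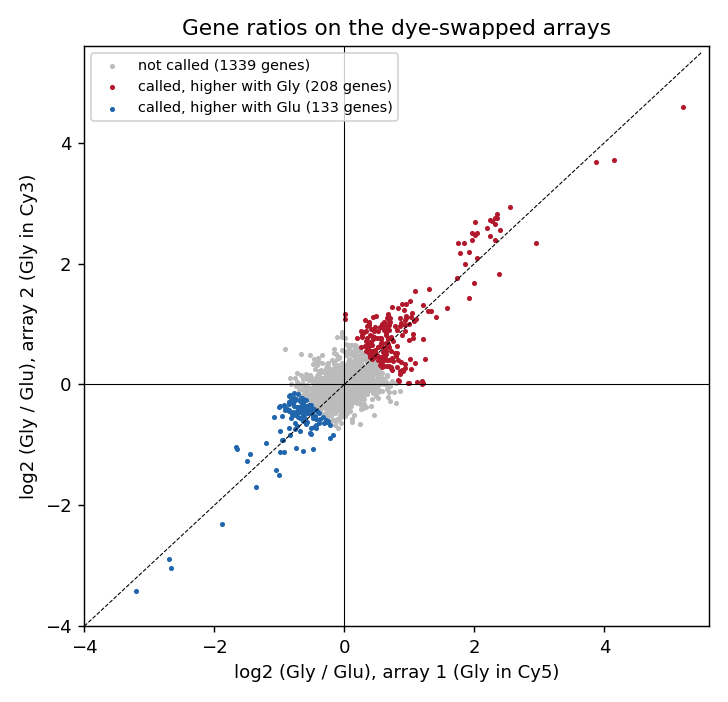
Each point is a gene, placed by its log2 ratio of Gly over Glu on array 1 (x axis, Gly in Cy5) and on array 2 (y axis, Gly in Cy3). The dashed line marks equal ratios; the 208 genes called higher with Gly (red) and the 133 called higher with Glu (blue) lie on the same side of 0 on both arrays, and 1339 genes (grey) were not called.

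Genes with neighbouring ID numbers changed together. A run was defined, after the ratios were seen, as at least 3 genes with consecutive ID numbers that were all called in the same direction. There were 31 such runs with 185 of the 341 calls (54.3%), of which 19 runs with 137 genes were higher with Gly and 12 runs with 48 genes were higher with Glu. In 10000 permutations of the genes over the ID numbers, the median was 10 genes in runs and the highest value 37 (permutation p = 0.0001, one-sided, the smallest that these permutations can give). The number of genes in runs was 97 without background correction, 102 with the median of each spot's pixels and 553 after centring on the E1A control spots. The split of runs also depended on the scaling. It was 14 higher with Gly and 9 with Glu under median centring, 11 and 16 without normalization and 83 and 3 after E1A centring. What order the ID numbers follow is not given in the sources used here.

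The longest run held 24 genes, all higher with Gly, with a mean log2 ratio of 2.00 ± 0.21 (SD, n = 2). Its genes ranged from 0.63 to 2.58, and 20 of them were at least 2-fold higher. A second run of 22 genes higher with Gly had a mean of 0.91 ± 0.15 (SD, n = 2), with 8 genes at least 2-fold higher. The steepest long run held 8 genes with a mean of 2.50 ± 0.17 (SD, n = 2), from 1.67 to 3.93, all at least 2-fold higher with Gly. LR1RLRE01360 belonged to it, beside a neighbour at 3.77. LR1RLRE00092 belonged to a run of 3 genes whose other members were at 0.73 and 1.28. Further runs of 14, 13 and 8 genes higher with Gly had means of 0.84, 0.71 and 0.78. The permuted ID numbers gave no run longer than 8 genes.

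Runs of genes higher with Glu were shorter. The longest held 7 genes with a mean log2 ratio of -1.21 ± 0.07 (SD, n = 2), against at most 6 genes in a run higher with Glu among the permutations (permutation p = 0.0001, one-sided, again the smallest possible). Its genes were uneven, with LR1RLRE00827 and a neighbour at -2.79 far below the other 5, which reached as close to 0 as -0.43. A run of 6 genes around LR1RLRE00555 had a mean of -1.42 ± 0.14 (SD, n = 2), with 3 genes at least 2-fold lower with Gly. A run of 5 genes had a mean of -1.02 ± 0.10 (SD, n = 2). Of the genes at least 2-fold apart on both arrays, 37 of the 42 higher with Gly and 9 of the 11 higher with Glu lay in runs. The 13 runs of at least 5 genes kept the sign of their mean under median centring, without normalization and with flagged spots kept. Runs hold only called genes, so their means start away from 0 and this check is weak. Of the 19 runs higher with Gly and the 12 higher with Glu, 8 and 6 were still called in full under median centring, and 5 and 8 without normalization. Fewer were called in full without background correction, at 2 and 3, and with the median of each spot's pixels, at 4 and 3. Centring on the E1A control spots moved the median log2 ratio of all genes to 0.40, a uniform shift that could turn no call. Under it only 19 of the 133 genes called higher with Glu, and 1 of the 12 runs higher with Glu in full, were still called.

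**Figure D2:**
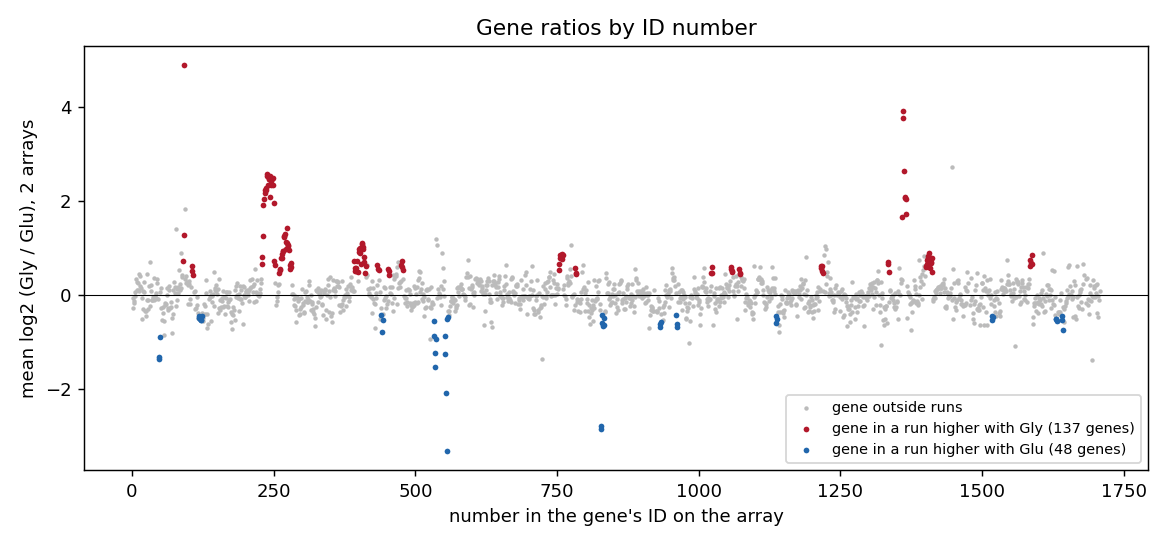
Mean log2 ratio of Gly over Glu of each gene over 2 arrays (y axis) by the number in its ID (x axis), with the 137 genes in runs higher with Gly in red, the 48 in runs higher with Glu in blue and all other genes in grey. The runs with the largest ratios stand apart from the band of other genes around 0.

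**Figure D3:**
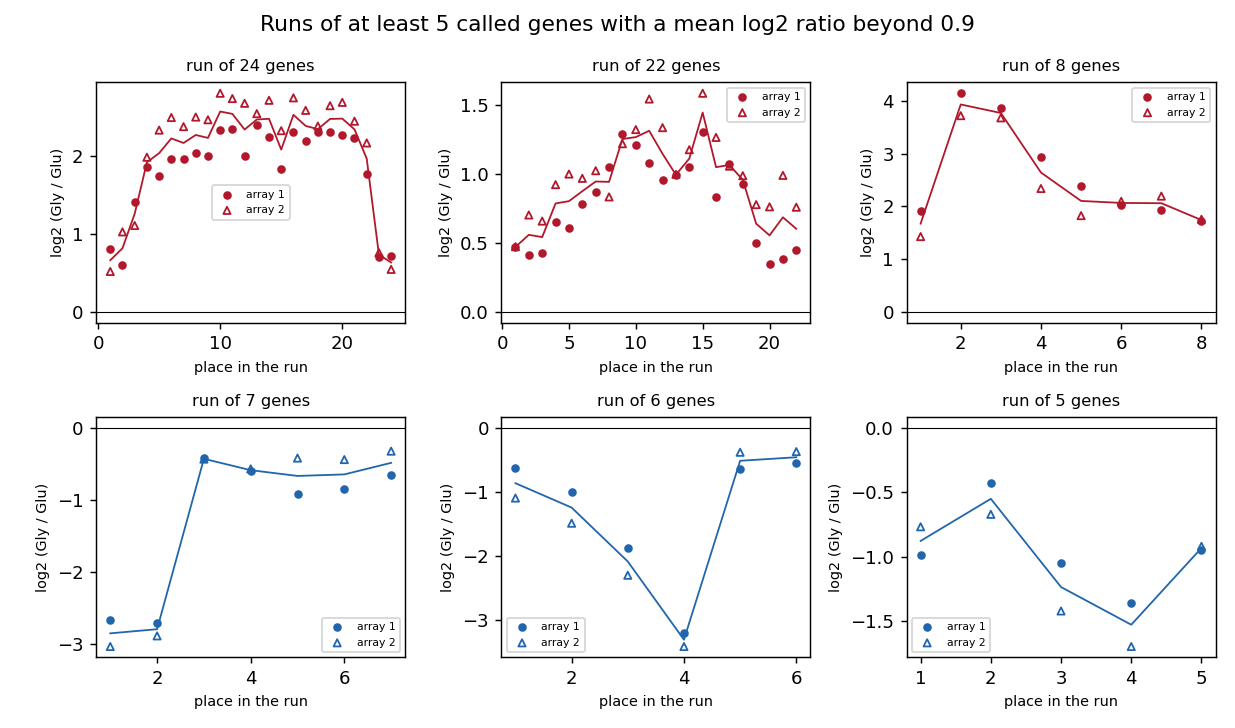
Log2 ratio of Gly over Glu (y axis) of each gene by its place in the run (x axis), for the 6 runs of at least 5 genes with a mean log2 ratio beyond 0.9 in either direction; filled circles are array 1, open triangles array 2 and the line their mean. The runs of 24, 22 and 8 genes lie above 0 and those of 7, 6 and 5 genes below 0 on both arrays.

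The ratios of the 2 arrays, turned to the same direction, had a Pearson correlation of 0.806 and a Spearman correlation of 0.612 across the 1680 genes, which are not independent replicates. Of these, 1183 genes (70.4%) had the same sign on both arrays. The correlation was 0.656 among the 560 dimmest genes, 0.696 among the next 560 and 0.866 among the 560 brightest, which also held 178 of the 341 calls. The difference between the arrays divided by 2 holds dye effects and noise but no difference between Gly and Glu that is the same on both arrays. If the arrays held RNA of different cultures, it would also hold differences between these. Across all 1680 genes, its size reached that of the smallest call for 25 genes, whereas the mean did so for 341. For no gene did it reach a 2-fold size, and its largest value was 0.75. Its SD across genes was 0.124 among the dimmest 560 genes, 0.165 among the next 560 and 0.195 among the brightest 560. The higher correlation among the brightest genes thus did not come with a smaller spread between arrays. The test used the same SE of 0.16 for all genes.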

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

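The tests on the reversed dyes, on the spread between E1A probes and on the amount of control material were chosen only after the E1A ratios were seen.

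The E1A control spots, which were left out of the main comparison and used only to centre 1 alternative, gave a signal above that of the negative control spots. Each of the 10 probes was summarised by its median net intensity over 15 spots in each channel of each array. These medians ranged from 59.4 to 2671, with a median of 199.7. The negative control probe, with 79 spots, had channel medians of 5.57 to 17.3, with a median of 8.47. What the E1A probes detect, and whether matching RNA was added to the samples, is not given in the sources used here. After loess, 3 probes of the eQC control set with 24 spots each had log2 ratios of Gly over Glu of -0.32 to -0.20 on array 1 and -0.16 to -0.09 on array 2. The other 37 eQC probes, which were dimmer, lay below 0 on array 1 and above 0 on array 2. The Pro25G probes had medians of -2.81 and 1.83 and the BrightCorner probe of -2.64 and 1.71 on arrays 1 and 2. Their signs turned with the dyes, yet their means over both arrays were -0.49 and -0.47. The ratios of these probes thus did not cancel fully in the mean, and the cause was not tested.

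The E1A spots were brighter with Glu on both arrays, at a net ratio of Gly over Glu of 0.628 on array 1 and 0.728 on array 2. A bias of the dyes would turn the sign on array 2, where the median log2 ratio after loess remained at -0.28 against -0.53 on array 1. Of 1000 random sets of 10 gene probes of like brightness, 0% had so low a median. Loess was fitted on gene spots and centres their ratios at each brightness. These sets therefore cannot decide whether a bias with brightness was left in the control spots. Hybridisation of 10 different bacterial transcripts is argued against by the narrow SD of 0.0778 between E1A probes, against a median of 0.28 in sets of gene probes. A single transcript binding all 10 probes stays open. An unequal amount of control material or of bacterial RNA may account for the median of -0.39 over both arrays, taken after normexp with its offset and loess. The net ratios equal log2 values of -0.67 on array 1 and -0.46 on array 2, so the size depended on the processing. An unequal amount cannot be told apart from a difference in messenger RNA per cell, because the labels give no added amounts. No biological explanation was tested.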

How the results depend on the processing

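The E1A centring, the averaging of probes first, the minimum of 3 unflagged spots, the threshold from the difference between arrays and all values on neighbouring ID numbers were chosen only after the data were seen. The 341 calls became 179 without background correction (120 higher with Gly, 59 with Glu), 201 with the median of each spot's pixels (135 and 66), 63 when a 2-fold mean change was also required (49 and 14) and 760 after centring on the E1A spots (741 and 19), which moved the median log2 ratio of all genes to 0.40. Of the 179 calls 174 were among the 341 with the same sign, as were all 201 of the second setting. Of the 341 calls, 275 remained with median centring, 266 without normalization, 267 in the value table and 227 after E1A centring, 208 higher with Gly and 19 with Glu (the cause of these changes, apart from the uniform shift by E1A centring, and of the shifts given next, was not tested). The other settings gave 232 to 350 calls. The 53 genes at least 2-fold apart on both arrays became 31 without background correction (27 higher with Gly, 4 with Glu) and 96 after E1A centring (92 and 4). They became 66 to 82 when either array was used alone, where a gene has to pass on 1 array only. The correlation of the arrays was 0.848 without background correction, 0.769 with median centring or no normalization and 0.774 in the authors' value table. Under the settings computed for single genes, the 4 named genes kept their sign and were called wherever there was a test, with log2 ratios of 4.06 to 5.29 for LR1RLRE00092, which the minimum of 3 spots left out, 3.22 to 4.32 for LR1RLRE01360, -3.66 to -2.89 for LR1RLRE00555 and -3.07 to -1.92 for LR1RLRE00827. Their largest adjusted p under these settings was 9.95e-05 with limma; values under the intensity trend, robust eBayes, the test by probe and the threshold from the difference between arrays were not computed for them. The correlation of adjacent ID numbers ranged from 0.675 to 0.734, and 97 to 553 genes lay in runs. The filter on dim spots changed none of these values, since signals exceeded background nearly everywhere, so it tests nothing. A dye term gave the same values without a test, as it must with 2 arrays of reversed dyes, so it tests nothing either. Tests of gene lists were not run because no ID had a name.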

Other observations

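The test on transcription of neighbouring genes together was chosen only after the run pattern was seen, as were the counts of neighbouring pairs and the stretch of 53 genes, and the bootstrap of the brightest genes was chosen after their ratios were seen.

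The 2 longest runs of genes higher with Gly, of 24 and 22 genes, lay close together. A stretch of 53 consecutive ID numbers held both, and 46 of its genes were called higher with Gly, or 22.1% of all 208 such calls. The stretch was set to span these runs, so its 46 calls follow from their lengths. Of the 53 ratios, 50 were above 0. The 7 genes between the runs had a mean log2 ratio of 0.06 and a lowest value of -0.20, so the stretch was broken by genes with ratios near 0. Its mean was 1.29. The run of 24 genes rose from low values at its start to a plateau and ended in lower values again, and the run of 22 genes never reached the plateau of the other, with a highest gene at 1.44.

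Called genes with adjacent ID numbers rarely went in opposite directions. Of such pairs 184 had the same direction, against a median of 36 in permuted ID numbers, and 7 had opposite directions, against a median of 32 (permutation p = 0.0001 for each, one-sided, the smallest that the permutations can give). The correlation between the ratios of genes fell with the distance of their ID numbers, from 0.704 for adjacent numbers to 0.390 at a distance of 5, 0.219 at 10 and -0.019 at 50. Nearly all of the largest changes lay in runs, with 24 of the 25 genes at least 4-fold higher with Gly and 4 of the 4 at least 4-fold higher with Glu.

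The tables argued against position on the slide and dye bias as sources of the correlation between adjacent ID numbers. Subtracting the median ratio of surrounding spots left it at 0.705, and spots of adjacent ID numbers lay as far apart on the slide as those of random genes, at a median of 52.5 against 53.1 spots. A dye bias of the probes would turn the sign between arrays, but a gene's ratio on one array correlated at 0.594 with that of the next ID number on the other. Permuting ratios among genes of like brightness gave at most 0.105. Loess had already centred these ratios at each brightness, so a low value was largely fixed beforehand. It shows only that a trend with brightness left after loess was too small to give the correlation. Transcription of neighbouring genes together, as in operons, may be the source but stays open, because whether the numbers follow the chromosome is not given. The brightness of adjacent ID numbers correlated at 0.533, above the highest value of 0.0814 in permuted genes. Transcription together would give such a value, but it does not decide, since other sources of shared brightness were not tested.

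Before loess, the brightest 168 genes lay lower with Gly than the median of all genes, with a median of -0.19 over the genes' means of both arrays. Saturation is argued against as the whole cause, since 119 of these genes with no spot over 10000 still lay at -0.15. A dye bias equal on both arrays cancels in such means and leaves only a gap between the arrays, whose medians were -0.36 on array 1 and -0.0797 on array 2 (95% bootstrap interval over genes -0.15 to 0.00163). Because the interval on array 2 reaches 0, a trend of array 1 alone cannot be told apart from a lower share of abundant transcripts with Gly. Without loess, the split of calls changed from 208 higher with Gly and 133 with Glu to 164 and 146 under median centring. It also depended on the centring, at 139 and 190 without normalization.

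Spots of the 53 genes at least 2-fold apart on both arrays were marked by the quantification software more often than other spots, at 5.97% against 2.59% on array 1 and 8.81% against 1.81% on array 2. Bright spots were marked more often in general, and 41 of the 53 genes were among the 560 brightest. Within these 560 genes the shares were 7.32% against 5.79% on array 1 and 11.0% against 4.52% on array 2.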
